A study of Mus musculus and Homo sapiens with 27 samples.

How the data were processed

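The series holds 27 arrays of the lymphochip, a spotted cDNA array of genes expressed in lymphocytes, each hybridised with RNA of 2 dyes. On the 23 mouse arrays, RNA of B cells grown in culture with lipopolysaccharide (LPS) for 0, 24, 48 or 96 h was labelled with Cy5, and a common reference pool with Cy3. Per the labels, the pool mixes RNA of B-cell, T-cell and monocyte lines. On the 4 human arrays, RNA of OCI-Ly7 cells carrying an IRF4 vector was labelled with Cy5, and RNA of OCI-Ly7 cells carrying an empty vector with Cy3. The design text of the series calls the human control non-transduced, while the labels call it an empty vector; the labels were followed. Total RNA was extracted with Trizol and labelled by reverse transcription, per the labels.

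The deposited values are log2 ratios of the channels of each array, 12292 features on the mouse platform and 15246 on the human platform, with no missing value. The base of the logarithm and the direction of the ratio are not given in the sources used here. Base 2 was taken from the range of the values, and the direction was taken as Cy5 over Cy3, sample over pool and IRF4 vector over empty vector. The planned checks of direction were Irf4 higher in Het than in KO and IRF4 higher with the IRF4 vector. Irf4 was not among the named mouse features, so Cd79b was used in its place. Cd79b, a B-cell receptor gene that such a mixed pool should hold at a lower level, lay above the pool on 23 of 23 mouse arrays. The human check was not met by the mean of the IRF4 features, as given below, so the human direction stays an assumption. If the ratio ran the other way, every difference below would change its sign. Scanner, background correction, normalization and quality filters are not given in the sources used here. Medians of the deposited arrays lay between -0.44 and 0.28 (log2) on the mouse platform and between -0.26 and -0.08 on the human platform. Signals of the single channels were not analysed here, so neither signal over background nor saturation could be checked. The number of arrays and their unequal spread, given below, limit the precision.

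Gene symbols came from the annotation columns deposited with the platforms. On the mouse platform 559 features had 1 symbol, 44 had several and 11689 had none. On the human platform 10169 features had 1 symbol, 4 had several and 5073 had none. The design text of the series says that only sequence-verified features were published and counts 701 of them on the mouse array. Each array was centred on its median over all features. The value of a gene was the mean of its features with 1 symbol, which gave 331 mouse genes and 4604 human genes. Of the mouse genes 222 had more than 1 feature, and of the human genes 2674. All genes were kept, since no filter was needed where no value was missing.

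Groups were taken from the array titles. For 3 arrays, KO at 24 h replicate 3 and KO at 48 h replicates 1 and 3, the title says KO and the channel fields say Het; the titles were followed. No array pair held identical columns. The highest correlation between 2 mouse arrays was 0.692 over all features. Over the named genes, the mean correlation of an array with the other mouse arrays lay between 0.30 and 0.60. Replicate numbers of KO and Het arrays were not used as pairs in the main fit. Of 10 pairs with 1 number, 5 had a correlation of their deviations over 0.1. These correlations lay between -0.17 and 0.51, with a median of 0.1 against -0.03 for other pairs. The Het groups at 24 and 48 h have 2 arrays, whose deviations from their mean mirror each other. A KO array then has opposite correlations with them, such as 0.51 and -0.51 for KO 48 h replicate 1. The contrast with other pairs is thus partly built in. Pairing or a shared batch at some times is therefore not excluded, and the replicate number was tried as a block. Each title carries a number of the authors' database. The mouse arrays fall into 3 ranges of it, the lowest with 5 arrays, the middle with 5 and the highest with 13. The lowest range holds Het at 0 h replicates 1 and 2, KO at 0 h replicate 1, and replicate 1 of Het and of KO at 24 h; the highest holds all 96 h arrays. The standard deviation of the deposited values was 1.35 to 3.10 in the lowest range, 1.12 to 2.38 in the middle range and 0.98 to 1.79 in the highest range.

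A model with 1 mean per genotype and time was fitted to the mouse genes with limma 3.58.1 in R 4.3.3 (with statmod 1.5.0), with moderated tests by empirical Bayes. The contrasts were KO minus Het at each time and averaged over the 3 LPS times, each LPS time minus 0 h within each genotype, and the difference of these responses between genotypes. The human genes were tested by limma against a ratio of 0 over the 4 arrays. Only 1 dye orientation was hybridised, so a dye bias of a human gene cannot be separated from its ratio, and the spread of the control alone is unknown. All tests were 2-sided. P-values were adjusted by Benjamini and Hochberg within each comparison, with a threshold of 0.05. The design text speaks of biological repeats and the labels of repeats; neither says whether these were separate mice or cultures, so the p-values measure the spread between arrays, which may be technical.

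The groups of genes were 16 lists: plasma cell, endoplasmic reticulum (ER) secretion and unfolded protein response, mature B-cell identity, MHC class II, switching and mutation, germinal centre, proliferation, MYC growth and metabolism, NF-kB activation, interferon response, apoptosis and survival, T and NK cell markers, myeloid markers, erythroid and platelet markers, immediate early stress, and ribosomal and housekeeping genes. A list was tested by fry of limma where at least 5 members were measured, which held for 7 lists on the mouse platform and 16 on the human platform, with adjustment over these lists. The fry test asks whether the members move, on balance, in 1 direction; it does not compare them with other genes. The camera test of limma with a correlation estimated from the arrays was run beside it. Agreement of direction between the platforms was measured across genes with 1 symbol on each, with 100000 permutations of the genes.

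The contrasts, lists, most of the tests and alternatives below and the rule for the genes named in the text were fixed before the data were examined. Fisher's exact test was planned on the signs of genes past the threshold in both species. There were 0 such genes at 96 h, and it was run on all genes measured on both platforms instead. The rule named, for the genotype contrasts, Het at 96 h against 0 h and OCI-Ly7: Irf4; the 10 highest and 10 lowest genes past the threshold, or the 5 smallest p-values each way where fewer than 5 passed; the 4 members of each list with the smallest p; and a set of regulators and markers of B cells and plasma cells. For the other contrasts it named the 3 highest and the 3 lowest past the threshold. The text leaves out some of the genes the rule gives, and says so where a gene outside it was chosen after its values were seen.

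The tests were tried on simulated data with known changes, using the group sizes of these arrays and the spread of each gene. The genes were simulated as independent and normal, with the same spread on every array. Wider arrays and correlated genes were thus left out. With 60 of 331 mouse genes changed between KO and Het at 96 h, 25.0% of changes of 1 log2 unit, 71.5% of changes of 2 and 93.0% of changes of 4 were recovered, and 2.94% of the calls were false. With 200 of 4604 human genes changed, 4.93%, 54.1% and 89.0% were recovered, and 4.93% of the calls were false. These rates hold for such simulated data and may not hold for the real arrays, where another split of the 0 h arrays gave 48 genes.

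The alternatives tried were the values as deposited, quantile normalization, tests of single features, other handling of the arrays with conflicting labels, the replicate number as a block, the database range as a factor, groups fitted alone, robust empirical Bayes, a minimum change of 1.5-fold, the day as a covariate or day 3 alone in OCI-Ly7, the camera test, and leaving out each array. After the data were seen, 6 more were added: centring over the named features, array weights, the median of the features of a gene, values beyond 6 log2 units set to missing, the fit without the 5 arrays of the lowest database range, and the fit of the highest range alone. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.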

Results

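RNA levels were measured in mouse B cells stimulated with LPS, a bacterial product that drives B cells to divide and to become antibody-secreting plasmablasts, and in OCI-Ly7, a human diffuse large B-cell lymphoma line. The mouse cells lacked Irf4 on both alleles (KO) or on 1 allele (Het). IRF4 is a transcription factor known to be required for plasma cell formation and isotype switching, which the series title names as its subject. Het cells had 3 arrays at 0 h, 2 at 24 h, 2 at 48 h and 4 at 96 h, and KO cells had 3 at each time. OCI-Ly7 cells with an IRF4 vector were compared with empty-vector cells on 1 array at day 2, 2 at day 3 and 1 at day 5. Mouse values are log2 ratios over a pool of lymphoid and myeloid cell lines, so a mouse level of 0 means the level of that pool, and human values are log2 ratios over the empty vector. Irf4 itself was not among the named mouse features, so its loss could not be checked on the arrays.

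The comparison of KO with Het at 96 h asked which genes differ between the genotypes late in the LPS response, when plasmablasts form. Jchain, which encodes the joining chain of secreted IgM and IgA, lay at 4.05 ± 0.18 (SD, n = 4) in Het and at -3.36 ± 0.36 (SD, n = 3) in KO. It was 170-fold lower in KO, a log2 difference of -7.41 ± 1.17 (SE, limma adjusted p = 0.000495). Jchain was lower in KO before LPS too, as given below for 0 h, where the size of the difference rests in part on a very low KO array. The fall is thus not shown to be particular to the late response. Iglv1, an immunoglobulin lambda variable segment, was lower by -2.30 ± 0.58 (SE, adjusted p = 0.0345), on 2 features that related lambda segments may share. Socs2, a cytokine-induced inhibitor of JAK-STAT signalling, was 15.5-fold lower at -3.96 ± 0.42 (SE, adjusted p = 7.37e-06). Entpd1, the ectonucleotidase CD39, was lower by -1.47 ± 0.32 (SE, adjusted p = 0.0116).

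In all, 9 of 331 genes were past the threshold at 96 h, 0 higher and 9 lower in KO, and 30 had an unadjusted p under 0.05. The other 5 were Ints7, a subunit of the Integrator complex (-3.29), Trim65 (-3.23), Trim27 (-3.57), Adck1 (-3.21) and Med9, a Mediator subunit (2.84-fold lower). Of these 9 genes, Jchain and Iglv1 are members of the plasma cell list, and all but Iglv1 rest on 1 feature each. Jchain, Socs2, Ints7, Trim65, Trim27 and Adck1 were past the threshold in 22 of 22 alternatives. The Iglv1 and Med9 calls were lost without Het 96 h replicate 2, 3 or 4 or any KO 96 h array, with adjusted p up to 0.164 and 0.179. The Entpd1 call was lost without KO 96 h replicate 1 or 2 (adjusted p = 0.0712 and 0.0597).

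The plasma cell list fell as a group at 96 h. Of its 8 measured members 7 were lower in KO, 2 past the threshold and 4 when adjusted over the list alone, with a median of -1.36 and a fry adjusted p of 0.00128. The call held with an estimated correlation (adjusted p = 0.0188). In the same comparison markers of other cell types lay higher in KO. These were 3 of 3 T and NK genes with a median of 1.18 and 2 of 2 myeloid genes with a median of 0.76. Of them 0 were past the threshold, and 1 myeloid gene was when adjusted over the list alone. Xbp1, the transcription factor of the secretory programme, lay at -1.36 ± 0.47 (SE, adjusted p = 0.184), and Slc3a2, the heavy chain of an amino acid transporter, at -1.35 ± 0.40 (SE, adjusted p = 0.0991). Prdm1, which encodes the plasma cell repressor Blimp-1, differed by -0.91 ± 1.64 (SE, adjusted p = 0.993). Its SE is larger than its difference, so neither a change nor its absence can be read from it.

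Among the 10 genes of the ER secretion list, 9 were lower in KO at 96 h, 0 past the threshold and 1 when adjusted over the list alone, and the list had a fry adjusted p of 0.0731. Dnajc3, an ER co-chaperone, differed by -1.07 ± 0.29 (SE, adjusted p = 0.0646), and Herpud1, a factor of ER-associated degradation, by -1.23 ± 0.64 (SE, adjusted p = 0.629). The mature B-cell list was not past the threshold (adjusted p = 0.866). Of its 5 members, Cd79b, a chain of the B-cell receptor, differed by -0.42 ± 0.36 (SE) and Id3, an inhibitor of E proteins, by -0.65 ± 0.41 (SE). In the main limma fit, with 1 mean per genotype and time over all mouse arrays, no gene was past the threshold in the higher direction. Under alternatives the split was 10 higher and 32 lower with array weights, 3 and 26 without the lowest database range, 2 and 25 with only the highest, 2 and 23 with only the 96 h groups fitted, 1 and 17 after quantile normalization and 1 and 13 with arrays centred over the named features. Higher in KO without passing it were, among others, Hs2st1 at 1.70 (adjusted p = 0.230), Tyrobp, an adaptor of myeloid and NK cell receptors, at 1.48 (adjusted p = 0.359), the kinase gene Ikbke at 1.29 (adjusted p = 0.156) and the scaffold gene Akap12 at 0.99 (adjusted p = 0.389). Pim1, a survival kinase, lay at -1.29 (adjusted p = 0.389). Tyrobp is a marker of other cell types and did not pass the test; its level was 0.59 ± 0.37 (SD, n = 3) in KO and -0.89 ± 0.63 (SD, n = 4) in Het.

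**Figure D1:**
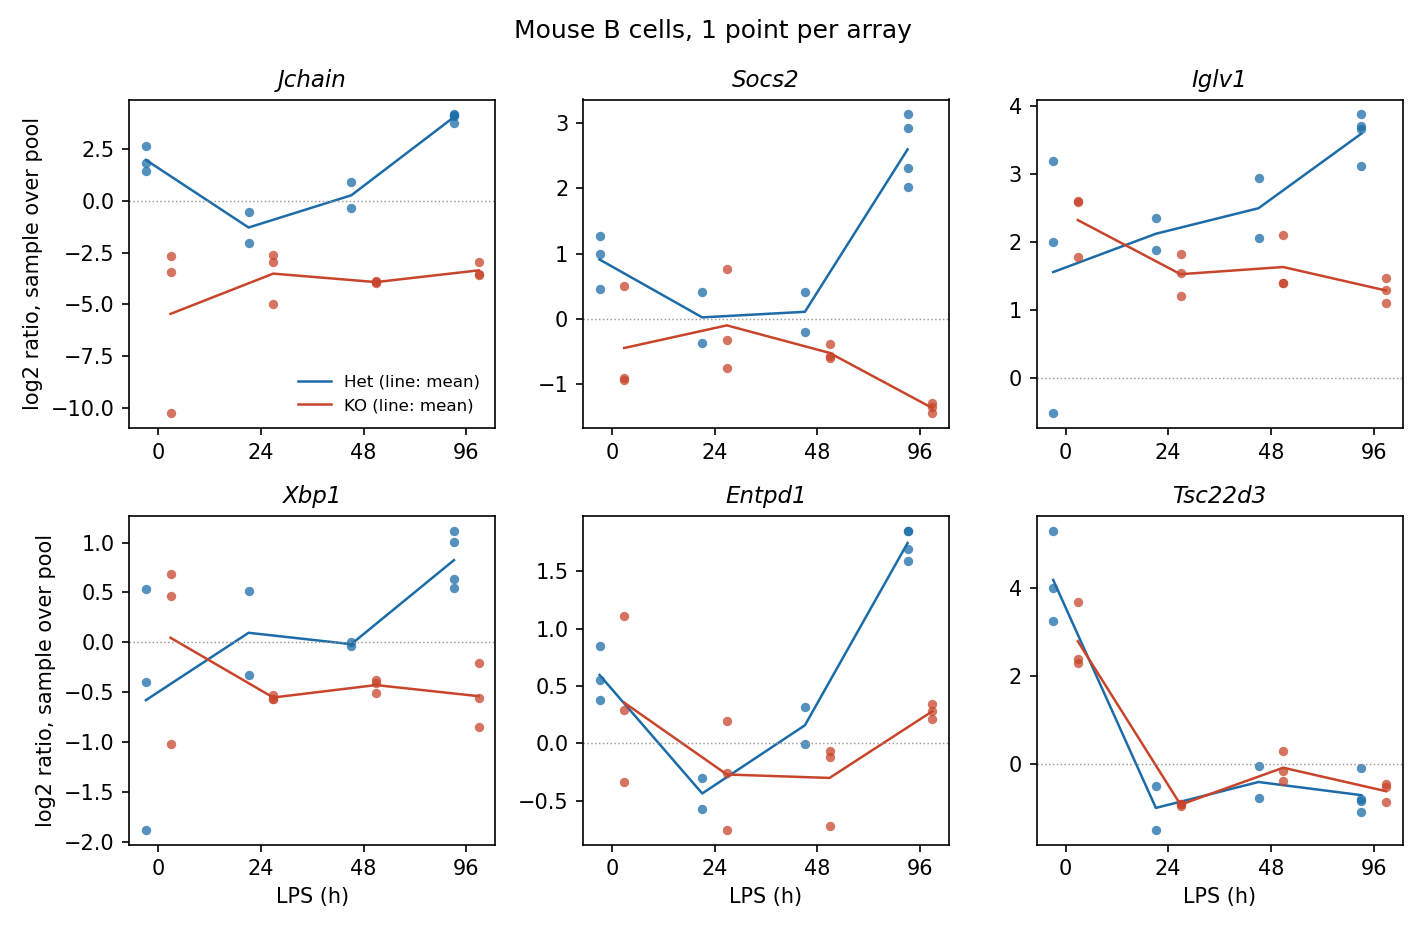
Levels of 6 genes in LPS-stimulated Het and KO B cells, as log2 ratio over the reference pool (vertical axis) against hours of LPS (horizontal axis), with 1 point per array and lines through the group means. Jchain means at 96 h lie at 4.05 in Het and -3.36 in KO, while Tsc22d3 falls from 0 h in both genotypes.

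Averaged over 24, 48 and 96 h, KO differed from Het in 8 of 331 genes, 0 higher and 8 lower, with 38 at an unadjusted p under 0.05. Jchain was 24.4-fold lower at -4.61 ± 0.77 (SE, adjusted p = 0.00251). Socs2 (-1.57), Adck1 (-2.12), Ints7 (-1.58), Trim65 (-1.66) and Trim27 (-2.16) were lower with adjusted p of 0.00251 or 0.00259. Alpl, the tissue-nonspecific alkaline phosphatase, was lower by -1.67 ± 0.36 (SE, adjusted p = 0.00971), and Dnajc3 by -0.78 ± 0.19 (SE, adjusted p = 0.0328). The plasma cell list (fry adjusted p = 0.00197; 1 of 8 lower past the threshold, 4 adjusted over the list alone) and the ER secretion list (0.0263; 1 of 10, 1 adjusted over the list alone) fell. Neither call held, with adjusted p = 0.147 and adjusted p = 0.701 with an estimated correlation. Slc3a2 (-0.94, adjusted p = 0.0757), Herpud1 (-1.15, 0.268), Xbp1 (-0.81, 0.316), Fes, a tyrosine kinase gene (1.51, 0.336) and S100a6, a calcium-binding protein gene (0.75, 0.391) were not past it. The count was 16 without Het 24 h replicate 2, and with arrays centred over the named features it was 5 higher and 10 lower. The Alpl call was lost without Het 24 h replicate 1 (adjusted p = 0.074), and the Dnajc3 call without 13 of 17 arrays in turn, with adjusted p up to 0.220 without Het 24 h replicate 1. The ER call was lost without Het 24 h replicate 1 or 2, Het 48 h replicate 1 or KO 48 h replicate 2, with adjusted p up to 0.121. It was also lost with the replicate block (0.0948), without the lowest database range (0.0686) and with the conflicting labels left out (0.0666). With the 3 arrays of conflicting labels taken as Het, 3 genes passed. The plasma cell and ER calls were then lost, each with an adjusted p of 0.078. On these arrays, KO 24 h replicate 3 and KO 48 h replicates 1 and 3, Jchain measured -2.98, -4.00 and -3.92, below each Het array (-2.02 or above) and on the side of the other KO arrays (-2.59 or below). The gene was chosen after its values were seen.

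At 24 and 48 h alone no gene was past the threshold between KO and Het in the main fit. Jchain differed by -2.23 ± 1.40 (SE, adjusted p = 0.426) at 24 h and by -4.19 ± 1.40 (SE, adjusted p = 0.997) at 48 h, where its levels were 0.27 ± 0.88 (SD, n = 2) in Het and -3.93 ± 0.06 (SD, n = 3) in KO. By limma 0 of 331 genes were past the threshold at either time, with 31 and 9 at an unadjusted p under 0.05. With values beyond 6 log2 units set to missing, 1 gene passed at each time, lower in KO. With only the groups compared fitted, 0 passed at 24 h and 1, lower in KO, at 48 h. The adjusted p of 0.997 for Jchain at 48 h does not show that its levels were alike. At 24 h the smallest p-values belonged to Pigv, an enzyme of GPI anchor synthesis (4.38), Traf4 (2.38) and Ncf1, a subunit of the phagocyte oxidase (4.26), all higher in KO, and to Adck1 (-2.19), Trim27 (-2.31) and the E protein gene Tcf4 (-1.31), all lower, with an adjusted p of 0.420. Alpl (-1.61) and Myc (-1.66) had that adjusted p too. Without Het 24 h replicate 2, 21 genes passed, and the median difference of all genes at 24 h was -0.49 log2 units, against 0.01 with arrays centred over the named features.

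At 48 h the histone deacetylase gene Hdac1 (2.60), the transcription factor gene Ets1 (1.52), S100a6 (1.26) and Lgals3bp (1.08) were the higher ones, and Alpl (-1.43), Gstt2 (-0.97) and Dnajc3 (-0.74) the lower ones, all with an adjusted p of 0.997. Of the 8 plasma cell genes 0 were above 0 at 48 h, with a fry p of 0.0318 before and 0.223 after adjustment, while camera gave adjusted p = 0.0488 with an estimated correlation. The Het groups at these times have 2 arrays each, and of the 3 KO arrays 1 at 24 h and 2 at 48 h carry conflicting genotype labels. The Hdac1 difference was -0.51 when the latter were taken as Het.

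The comparison at 0 h asked how the cells differed before LPS. Jchain was lower in KO by -7.44 ± 1.25 (SE, adjusted p = 0.00431), at -5.46 ± 4.18 (SD, n = 3) against 1.98 ± 0.62 (SD, n = 3) in Het. The lowest KO array lay at -10.27, which widens the spread and pulls down the KO mean at 0 h. Jchain was thus lower in KO before LPS too, but the size of that difference rests in part on 1 array. Its likeness to the -7.41 at 96 h therefore carries little weight. Higher in KO were Nars, the asparaginyl-tRNA synthetase (5.53), Mt2, a metallothionein (4.32), Idh1, the cytosolic isocitrate dehydrogenase (3.73), Ctps, the CTP synthetase (3.33), and Gbe1, the glycogen branching enzyme (2.57), with adjusted p between 0.0109 and 0.0348. These 5 genes lay low in Het at 0 h with a wide spread, such as Nars at -6.08 ± 3.69 (SD, n = 3) against -0.55 ± 0.36 (SD, n = 3) in KO. In all, 6 of 331 genes were past the threshold, 5 higher and 1 lower, with 57 at an unadjusted p under 0.05. Not past it were the thymidine kinase gene Tk1 (2.28, adjusted p = 0.0793), the B-cell scaffold gene Bank1 (-1.30, 0.101), Jun (-1.57, 0.140), the protease inhibitor gene Slpi (-3.05, 0.143), Socs2 (-1.35, 0.149) and Prdm1 (-3.48 ± 1.76 (SE), 0.321).

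The Jchain call at 0 h was kept without each array in turn, but lost without the lowest database range (adjusted p = 0.0509) and with only the 0 h groups fitted (adjusted p = 0.8), and the higher calls depended on single arrays. Without Het replicates 1, 2 and 3 in turn, 26, 1 and 57 genes passed, and without KO replicates 1 and 3, 1 and 4. Het replicates 1 and 2 and KO replicate 1 belong to the lowest range of database numbers, whose values were the widest. A fit without that range has 1 Het and 2 KO arrays at 0 h. With only the 0 h groups fitted 0 genes passed. Without the lowest range 2 genes passed, none of them Jchain, Nars, Mt2, Idh1, Ctps or Gbe1, and the median difference of the latter 5 was 0.87 in place of 3.73, with adjusted p between 0.317 and 0.865. The split was 3 higher and 2 lower with arrays centred over the named features, and 2 and 2 after quantile normalization. With values beyond 6 log2 units set to missing it was 0 higher and 1 lower, and Gbe1 lay at -0.21, but this setting takes out very low Het values that make up such differences. Of the lists, 0 of 7 were past the threshold at 0 h.

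The response of Het cells to LPS was the reference for the loss of Irf4. From 0 to 96 h, Tsc22d3, which encodes the glucocorticoid-induced leucine zipper and is high in resting B cells, fell by 4.90 on the log2 scale (29.9-fold; adjusted p = 7.32e-07), and Akap12 by 3.74 (adjusted p = 4.75e-06). Mzb1, an ER co-chaperone of immunoglobulin assembly, rose by 5.47 ± 1.60 (SE, adjusted p = 0.0201), the transcription elongation factor gene Ell2 by 2.53 ± 0.76 (SE, adjusted p = 0.0218), Iglv1 by 2.03 ± 0.58 (SE, adjusted p = 0.0191) and Xbp1 by 1.40 ± 0.47 (SE, adjusted p = 0.0345). Of 8 plasma cell genes these 4 rose, and 4 when adjusted over the list alone (fry adjusted p = 0.0222; adjusted p = 0.248 with an estimated correlation).

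Of the 5 mature B-cell genes 3 fell, and 4 when adjusted over the list alone (fry adjusted p = 0.0132; adjusted p = 0.787 with an estimated correlation). Ets1, which restrains plasma cell formation, fell by 2.25, Btg1, an antiproliferative factor, by 1.58, while Cd79b differed by -0.81 (adjusted p = 0.105). Other genes that fell were Mbd2, a methyl-CpG binding protein (-2.40), Myc (-2.27), Add1 (-2.06), the mTORC1 activator Rheb (-2.02), Bckdha (-2.00), Hs2st1 (-2.00), Tagap1 (-1.96) and the interferon-regulated factor Irf1 (-1.52). The largest rises besides Mzb1 were Nars (5.16), Gramd1a (5.09), Fxyd5 (4.85), the UDP-galactose transporter gene Slc35a2 (4.65), Idh1 (3.88), Csf1 (3.80), the ETS factor gene Gabpa (3.75), Nup153 (3.33) and Bcl2a1d, an antiapoptotic BCL2 family member with close paralogs (3.20).

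In all, 85 of 331 genes were past the threshold between 0 and 96 h in Het, 26 higher and 59 lower, with 135 at an unadjusted p under 0.05. The median change of all genes was -0.42 log2 units, and 0.20 with arrays centred over the named features, which gave 54 higher and 39 lower. The count was 45, 35 and 172 without Het 0 h replicates 1, 2 and 3, 54 without Het 96 h replicate 1, and 16 without the lowest database range, where Slc35a2 lay at -0.00175. With only the Het 0 h and 96 h groups fitted it was 2. Without that range, which takes away Het 0 h replicates 1 and 2, the other named rises were Mzb1 1.14, Nars 0.90, Gramd1a 1.79, Fxyd5 1.33, Idh1 0.84, Csf1 0.39, Gabpa 1.85, Nup153 0.93 and Bcl2a1d 1.77. Of these Gramd1a, Gabpa and Bcl2a1d were past the threshold. Ell2 rose by 5.46. Without Het 0 h replicate 1 the calls of Mbd2 (-0.92), Myc (-1.71), Bckdha (-1.63), Hs2st1 (-1.83), Tagap1 (-1.57), Mzb1 (5.40), Slc35a2 (3.29), Nup153 (1.25) and Btg1 (-1.25) were lost. Without Het 0 h replicate 2 those of Bckdha (-1.80), Hs2st1 (-1.90), Tagap1 (-1.87), Mzb1 (3.38), Slc35a2 (3.69), Csf1 (2.16), Xbp1 (0.75) and Iglv1 (1.00) were lost, and the plasma cell and mature B-cell list calls, each with an adjusted p of 0.0995. In that fit Gramd1a (2.90), Fxyd5 (3.10), Idh1 (2.48), Gabpa (1.73) and Bcl2a1d (2.02) kept theirs at smaller values. The plasma cell call was also lost without Het 96 h replicate 3 or 4 (adjusted p = 0.051 and 0.0509) and with the conflicting labels left out or taken as Het (0.0825 and 0.065). The mature B-cell call was also lost without the lowest database range (0.480), with only the highest (0.436) and with the range as a factor (0.0923). Without Het 0 h replicate 3 the Ell2 call was lost (1.07) and Slc35a2 rose by 6.98. Leaving out 1 Het 96 h array ended the calls of Mbd2 (-2.20), Myc (-1.97), Slc35a2 (4.69) and Xbp1 (1.47) for replicate 1, of Slc35a2 (4.57) for replicate 2, and of Hs2st1 and Xbp1 for replicates 3 (-1.70 and 1.34) and 4 (-1.45 and 1.30).

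By 24 h of LPS, the proliferation list had risen in Het: 10 of 10 members were above 0, 6 past the threshold and 9 when adjusted over the list alone (fry adjusted p = 0.000261; adjusted p = 0.155 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose by 6.21 ± 1.88 (SE, adjusted p = 0.0345) and Tfdp1, the partner of E2F factors, by 5.63 ± 1.72 (SE, adjusted p = 0.0358). Tk1 (3.32), Pcna, the sliding clamp of DNA replication (2.43), and Mcm2, a subunit of the replicative helicase (2.14), rose too; these 3 were chosen after their values were seen. The MYC growth list (5 of 9 higher, 8 adjusted over the list alone; fry adjusted p = 0.00713) and the apoptosis and survival list (3 of 7, 3 adjusted over the list alone; 0.00396) rose, and the mature B-cell list (2 of 5 lower, 2 adjusted over the list alone; 0.00713) fell. The ribosomal and housekeeping list, which shares Gapdh with the MYC growth list, also lay higher, with 4 of 5 members above 0, 2 past the threshold, 3 adjusted over the list alone and a median of 1.46, against 1.80 for MYC growth, but it was not past the threshold (fry adjusted p = 0.0663). With an estimated correlation none of the MYC growth, apoptosis and mature B-cell calls held, at adjusted p = 0.262, adjusted p = 0.262 and adjusted p = 0.258 with an estimated correlation. Nars rose by 5.84, and Tsc22d3 (-5.19), Trp53inp1, a p53 target (-3.85), and Ets1 (-2.99) fell.

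At 48 h in Het, Nars (6.29), Idh1 (4.90) and Gramd1a (4.70) were the highest and Tsc22d3 (-4.60), Ets1 (-3.28) and Btg1 (-2.35) the lowest genes past the threshold. The mature B-cell list fell (2 of 5 lower, 2 adjusted over the list alone; fry adjusted p = 0.0072) and the proliferation list (2 of 10 higher, 5 adjusted over the list alone; 0.00478), the apoptosis list (2 of 7, 2 adjusted over the list alone; 0.0256) and the MYC growth list (2 of 9, 6 adjusted over the list alone; 0.0463) rose. With an estimated correlation they had adjusted p = 0.161, adjusted p = 0.161, adjusted p = 0.454 and adjusted p = 0.454. Counts were 44 genes at 24 h (35 higher, 9 lower) and 28 at 48 h (20 higher, 8 lower), with 103 and 81 at an unadjusted p under 0.05. They were 55 higher and 44 lower at 24 h and 39 and 27 at 48 h with arrays centred over the named features, and 11 and 6, and 20 and 4, after quantile normalization. Without Het 24 h replicate 1, 5 genes passed at 24 h, and without Het 0 h replicates 1 and 3, 71 and 69. At 48 h 3 and 13 passed without Het 48 h replicates 1 and 2, and 79 without Het 0 h replicate 3. With only the groups compared fitted, 0 genes passed at 24 h and 0 at 48 h by limma. Each LPS time shares the 0 h arrays of its genotype, so overlap between times carries no weight of its own.

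Of the genes named for Het at 24 h, the calls of Trp53inp1 (-2.46), Rrm2 (5.87), Nars (6.15), Tfdp1 (5.38), Pcna (2.02), Mcm2 (1.71) and Tk1 (2.94) were lost without Het 24 h replicate 1, and those of Rrm2 (6.55), Tfdp1 (5.88) and Ets1 (-1.74) without replicate 2. Without Het 0 h replicate 2, Rrm2 rose by 3.02 and Tfdp1 by 2.49 and both kept their calls. Without the lowest database range Rrm2 (2.64) lost its call, and Nars rose by 1.89. At 48 h those of Ets1 (-2.15), Nars (6.19), Idh1 (4.61) and Gramd1a (4.53) were lost without Het 48 h replicate 1, and those of Gramd1a (4.88) and Btg1 (-1.89) without replicate 2. Gramd1a rose by 2.51 without Het 0 h replicate 2. Without the lowest range Nars rose by 2.03, Idh1 by 1.87 and Gramd1a by 1.41, all past the threshold. In these fits a group of 1 array is assumed to vary like the other groups. Of the lists at 24 h, the mature B-cell call was lost without Het 24 h replicate 2 (adjusted p = 0.067) and without the lowest database range (0.116), and the MYC growth call without replicate 1 (adjusted p = 0.111) and after quantile normalization (0.131). At 48 h the apoptosis call was lost without Het 48 h replicate 1 or Het 0 h replicate 3 (adjusted p = 0.243 and 0.0789), with the conflicting labels left out (0.0575) and with only the highest range (0.0616). The mature B-cell call at 48 h was lost after quantile normalization (0.290), without the lowest range (0.147) and with only the highest (0.0616). The MYC growth call was lost without 14 of 27 arrays in turn, after quantile normalization (0.279), with the replicate block (0.0804) and with the conflicting labels left out (0.0901).

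In KO cells Tsc22d3 fell too, by 3.72 at 24 h (adjusted p = 0.000123), 2.88 at 48 h (adjusted p = 0.00365) and 3.41 at 96 h (adjusted p = 0.000405). At 24 h Mt2 (-4.70) and Trp53inp1 (-3.17) fell and Bcl2a1d (3.01) rose. At 48 h Pkm, the muscle-type pyruvate kinase (2.84), S100a6 (2.62) and the kinase gene Mapkapk2 (1.82) rose. At 96 h Akap12 fell by 2.11 (adjusted p = 0.019) and Slpi, a secreted inhibitor of neutrophil proteases, rose by 4.24 ± 0.95 (SE, adjusted p = 0.0347). Counts were 5 genes at 24 h (1 higher, 4 lower), 5 at 48 h (4 higher, 1 lower) and 3 at 96 h (1 higher, 2 lower), with 41, 27 and 81 at an unadjusted p under 0.05. The proliferation list was lower at 96 h than at 0 h, with 9 of 10 members below 0, 0 past the threshold and 3 when adjusted over the list alone (fry adjusted p = 0.042; adjusted p = 0.804 with an estimated correlation). That list call was lost in 21 of 39 alternatives.

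The KO counts were small and moved with scaling and with single arrays. With arrays centred over the named features the splits were 13 higher and 24 lower at 24 h, 10 and 5 at 48 h and 9 and 7 at 96 h. After quantile normalization they were 2 and 3 at 48 h and 2 and 68 at 96 h, and with the values as deposited 1 and 11 at 24 h and 2 and 7 at 96 h. The count at 24 h was 2 without KO 24 h replicate 1 or KO 0 h replicate 1, 3 without KO 0 h replicate 2 or 3, and 9 without KO 24 h replicate 2. At 48 h it was 1 without KO 0 h replicate 2 or 3 or KO 48 h replicate 1, and 2 without KO 48 h replicate 2 or 3. At 96 h it was 1 without KO 0 h replicate 1 or 2 or KO 96 h replicate 2 or 3. Tsc22d3 stayed past the threshold without each array in turn at all 3 times, and the other 8 calls named here were each lost without at least 1 array, with an adjusted p up to 0.257 for Trp53inp1.

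Whether KO cells responded to LPS differently from Het cells was tested by the interaction, with 0 of 331 genes past the threshold by limma at 24, 48 and 96 h and 26, 28 and 42 at an unadjusted p under 0.05. Among the genes with an unadjusted p under 0.05 at 96 h were Socs2 (-2.60 ± 0.61, SE, adjusted p = 0.0826), Ctps (-3.84 ± 0.89, SE, adjusted p = 0.0826) and Slpi (4.79 ± 1.31, SE, adjusted p = 0.0881), chosen after their values were seen. Ctps differed by -4.01 (adjusted p = 0.217) at 24 h and -3.79 (adjusted p = 0.273) at 48 h. Under other scalings the counts at 96 h were 1 higher and 13 lower by quantile normalization, 2 and 7 with arrays centred over the named features and 0 and 5 with the values as deposited, and at 48 h 3 and 0 with arrays centred over the named features. With arrays centred over all features, different counts in Het and KO are therefore not shown to be a difference of response. The 1 list past the threshold was proliferation at 24 h: 10 of 10 members responded less in KO, with a mean of -2.12, 0 past the threshold and 0 when adjusted over the list alone (fry adjusted p = 0.0287; adjusted p = 0.243 with an estimated correlation). At 0 h 10 of 10 members lay higher in KO, with a mean of 1.39 (fry adjusted p = 0.110), and at 24 h the mean difference was -0.74. By these means, which single members can carry, most of the -2.12 is the difference before LPS. Without Het 0 h replicates 1 and 3 the counts were 13 and 30 at 96 h, without Het 0 h replicate 2 there were 4, and without Het 0 h replicate 3 they were 10 at 24 h and 15 at 48 h. Without Het 24 h replicate 2 the count was 7 at 24 h. The proliferation call was lost without Het 24 h replicate 1, Het 0 h replicate 2 or 3, KO 24 h replicate 1, or KO 0 h replicate 1 or 2, with adjusted p up to 0.211. It was also lost after quantile normalization (0.364), with the range as a factor (0.0658), without the lowest range (0.141), and with the conflicting labels left out (0.0737) or taken as Het (0.0706).

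The human arrays compared lymphoma cells carrying an IRF4 vector with cells carrying an empty vector. IRF4 itself measured -0.03 ± 0.47 (SD, n = 4) over 4 features, whose means were -0.45, 0.02, 0.69 and -0.36, and only the feature at 0.69 was above 0 on 4 of 4 arrays. Higher IRF4 RNA from the vector was thus not registered by the mean of the features. The planned check of the direction of the human ratio by IRF4 was therefore not met, and that direction stays an assumption. The sequence carried by the vector is not given in the sources used here. TNFRSF17, the plasma cell receptor BCMA, was 10.3-fold higher at 3.36 ± 0.53 (SD, n = 4, adjusted p = 0.0455), above 0 on 4 of 4 arrays. BMP6, a bone morphogenetic protein, was higher at 3.25 ± 0.55 (SD, n = 4, adjusted p = 0.0455). FGFR2, a growth factor receptor measured by 1 feature, was 21.6-fold lower at -4.43 ± 0.18 (SD, n = 4, adjusted p = 0.00878), ICOSLG, the ligand of the T-cell costimulator ICOS, lay at -3.23 ± 0.59 (SD, n = 4, adjusted p = 0.0455) and SGSH, a lysosomal sulfamidase, at -2.82 ± 0.39 (SD, n = 4, adjusted p = 0.0455). Each of these 5 had its sign on 4 of 4 arrays.

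These 5 of 4604 genes were past the threshold, 2 higher and 3 lower, with 1099 at an unadjusted p under 0.05. The count was 0 without the day 2 array, day 3 replicate 1 or day 3 replicate 2 and 1 (FGFR2) without the day 5 array; it was 1 lower and 0 higher with the values as deposited and with arrays centred over the named features, and 21 higher and 73 lower after quantile normalization. Of 19 plasma cell genes 13 were above 0, 1 past the threshold and 8 when adjusted over the list alone, with a fry p of 0.00362 before and 0.058 after adjustment over 16 lists. SUB1, a transcriptional coactivator (3.25, adjusted p = 0.102), JCHAIN (2.50 ± 0.89, SD, n = 4, adjusted p = 0.102), XBP1 (2.07, 0.119), PRDM1 (1.83, 0.119) and the ectoenzyme gene CD38 (1.60, 0.129) had values above 0 on 4 of 4 arrays. In the ER secretion list 22 of 26 genes were above 0, 0 past the threshold and 5 when adjusted over the list alone (fry adjusted p = 0.264), among them SSR3 (1.87), CRELD2 (1.45), SSR1 (1.38) and LMAN1 (1.34).

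In the mature B-cell list 11 of 39 genes were above 0, 0 past the threshold and 2 when adjusted over the list alone, 1 each way (fry adjusted p = 0.276). CD79B, a chain of the B-cell receptor, measured -1.86 ± 0.76 (SD, n = 4, adjusted p = 0.123) and IKZF3 (Aiolos) -2.06 (adjusted p = 0.137), while BTG1 (1.60) and the complement regulator CD55 (1.32) lay above 0. CIITA, the master regulator of MHC class II genes, measured -0.45 ± 0.17 (SD, n = 4, adjusted p = 0.298), SPIB -0.42 ± 0.20 (SD, n = 4, adjusted p = 0.331), IRF8 -0.50, PAX5 -0.61 and MYC 0.82. Other genes with small p-values were P2RX6 (-3.97, adjusted p = 0.063), ARHGAP15 (-3.13, 0.063), SRSF10 (1.73, 0.102), BCAR3 (1.97, 0.102), REL (-2.48, 0.124), the germinal centre genes A4GALT (-2.35, 0.108) and SERPINA9 (-1.14, 0.137), and the glycolytic enzyme gene ENO1 (-1.64, 0.129). Day 3 alone gave 196 genes past the threshold, and a covariate for the day 39.

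**Figure D2:**
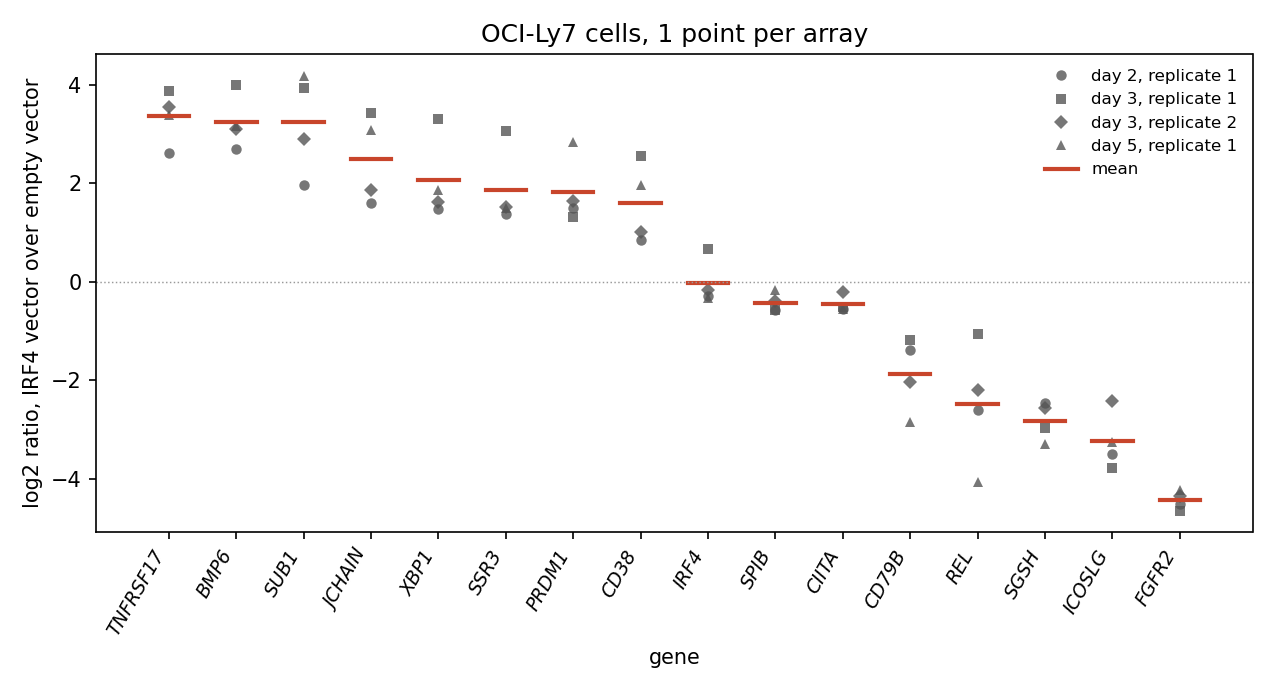
Log2 ratio of IRF4 vector over empty vector in OCI-Ly7 cells (vertical axis) for 16 genes (horizontal axis), with 1 point per array, shaped by day and replicate, and a bar at the mean. TNFRSF17 (mean 3.36) and BMP6 (3.25) lie above 0 and FGFR2 (-4.43), ICOSLG (-3.23) and SGSH (-2.82) below 0 on 4 of 4 arrays, and the IRF4 mean is -0.03.

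Differences between KO and Het in mouse cells were set against the ratios of IRF4 vector over empty vector in OCI-Ly7, where the mean of the IRF4 features did not register higher IRF4 RNA, across 217 genes measured on both platforms. Genes are not independent replicates, and the test permuted them. The correlation of the KO minus Het difference at 96 h with the human ratio was -0.08 (Spearman's rho, permutation p = 0.232), and -0.10 for the averaged difference (permutation p = 0.159). Pearson's correlation, which large single values can move, was -0.21 and -0.19 and was not tested. Of 125 genes lower in KO at 96 h, 64 lay above 0 with the IRF4 vector (Fisher's exact p = 0.891). Of the 9 genes past the threshold at 96 h, 4 were measured in OCI-Ly7: JCHAIN at 2.50 and ENTPD1 at 0.47, the opposite sign to KO, and INTS7 at -0.59 and SOCS2 at -0.19, the sign of KO. The number of these genes past the threshold in OCI-Ly7 was 0, with JCHAIN at an unadjusted limma p of 0.000709.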

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

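The tests on the late pattern, and at 0 h those of the lowest database range and of quantile normalization, were chosen after the result was seen; the tests with arrays centred over the named features, the tests of the proliferation list and the counts of sample splits were fixed before their results were seen. Readings of 3 tests were made stricter after their values were seen, each towards leaving the explanation open: the correlation of the late features, and both tests of the proliferation list, for which a value had to pass its bound by more than its SE.

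Of 331 genes, 9 were lower and 0 higher in KO than in Het at 96 h, Jchain among them. Noise of the wider arrays of the lowest and middle database ranges is a matter of the design here and was not tested. Of these ranges 0 arrays are in the 96 h groups, so they do not enter the differences and act only on the spread. Through the spread they do act on the calls, and with only the 96 h groups fitted 25 genes passed. Of 35 splits of the 7 arrays 1, the real one, gave as many, and the highest other split gave 4. A share of 1 in 35 is the smallest these arrays can give, and several comparisons were split without adjustment. Chance is thus less likely but not excluded. A shared or cross-reacting sequence behind Ints7, Trim65, Trim27, Adck1 and Socs2 stays open, because the median correlation of their 10 feature pairs within groups was 0.126, below the 0.531 of features sharing a gene name, but 0.814 without KO 24 h replicate 1, and the bound set for excluding it (0.842) lay above that median of features sharing a gene name. The loss of Irf4 is the explanation the design names and stays open, so the 5 features could count 1 change several times, while Jchain, Entpd1, Iglv1 and Med9 are outside that question.

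At 0 h 5 genes, Nars, Mt2, Idh1, Ctps and Gbe1, were higher in KO. Their median difference was 3.89 with arrays centred over the named features and 3.73 without that change. Idh1 (limma adjusted p = 0.0506) and Gbe1 (0.0685) were then no longer past the threshold. Such a change moves every gene of the comparison by the same amount. The choice between these 2 centrings thus does not account for the pattern, but it cannot decide on another shift per array. A scaling of the spread stays open: after quantile normalization the median was 2.55 and the mean 2.66 ± 0.70 (SE), above the bound of 2 by less than its SE, and Ctps, Mt2 and Gbe1 lost their calls. The wide values of the 5 arrays of the lowest database range may account for the pattern: without these arrays the median was 0.87 and the mean 0.84 ± 0.32 (SE), in place of 3.90 ± 0.76. That fit leaves 1 Het and 2 KO arrays at 0 h, with the spread taken from the other groups too. The range thus cannot be told apart from single arrays. With values beyond 6 log2 units set to missing, 0 genes passed higher and 1 lower. This setting takes out very low Het values, such as Nars at -8.28 on its lowest Het array, which make up the difference. The loss of calls under it therefore cannot decide whether these values are noise. The 6 arrays make 10 splits, too few for a share under 0.05; 3 gave at least the 6 genes of the real one, and the highest, 48, set KO replicate 1 and Het replicates 1 and 2 against the rest, which are the 3 arrays of the lowest range and a sign of structure in the samples. With the range as a factor Nars, Mt2, Ctps and Gbe1 passed and Idh1 did not (adjusted p = 0.0688), so a part from genotype stays open as well.

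The proliferation list differed between the genotypes in its LPS response at 24 h (fry adjusted p = 0.0287), with a mean of -2.12 ± 0.59 (SE) over 10 members. At 0 h the members lay higher in KO by a mean of 1.39, and at 24 h they differed by a mean of -0.74. By these means, which single members can carry, most of the -2.12 is the difference before LPS. Without the 5 arrays of the lowest database range the mean was -1.61 ± 0.60 (SE), and with arrays centred over the named features it was -1.78 ± 0.46 (SE). The first of these fits has 1 Het array at 0 h and 1 at 24 h, so its Het response is 1 array against 1. Both means lie below the bound set against these explanations, but by less than their SE. Neither the range nor the scaling can therefore be told apart from a genotype effect. Ctps (-4.01) and the other genes had no call at this time, and the list call was lost with an estimated correlation.

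Other splits of the samples were counted for the remaining comparisons of at least 3 arrays a group. For KO minus Het averaged over LPS times, 2 of 100 splits drawn gave as many genes as the real 8, the real one included. This share is under 0.05, but the highest other also gave 8 and only a part of the possible splits was drawn. Chance was therefore not excluded. For Het 96 h minus 0 h, 2 of 35 splits gave as many, with 85 in the real split and 86 in the highest other, so chance was not excluded. That other split set Het 0 h replicates 1 and 2, of the lowest database range, with Het 96 h replicate 4 against the rest, and with the range as a factor the real count was 20. In KO, 10 splits at each time are too few for a share under 0.05, with 1 as large at 24 h (5 genes; highest other 1), 1 at 48 h (5; 0) and 1 at 96 h (3; 0). For the interaction at 96 h, 100 of 100 splits gave at least the real 0, with a highest of 9, so the count carries no information.

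Single arrays far from the other 3 of their group were found for 3 of 45 genes in Het at 96 h and 3 of 32 genes in OCI-Ly7, where chance gives about 1 in 20. Bckdha measured -2.36 on Het 96 h replicate 4 against -0.41 to -0.25, a gap of 0.927 of the range. Fes measured -3.35 on Het 96 h replicate 3 against -1.19 to -0.77 (0.840). Mbd2 measured -0.83 on Het 96 h replicate 1 against -0.11 to 0.03 (0.834). CIITA measured -0.20 on day 3 replicate 2 against -0.50 to -0.56 (0.844). IRF4 measured 0.67 on day 3 replicate 1 against -0.17 to -0.32 (0.846). SSR3 measured 3.07 on day 3 replicate 1 against 1.52 to 1.38 (0.918).

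Among the mouse features with no gene name, which the gene comparisons leave out, 15 were past the threshold between KO and Het at 96 h when all 12292 features were tested. Of these 13 were lower in KO, by -6.86 to -2.27 log2 units, and 2 were higher.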

How the results depend on the processing

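Values that leave the call or move by more than 1.5 times are given here by setting, as numbers of genes past the threshold; the alternatives that were chosen after seeing the data are centring over the named features, array weights, gene medians, extreme values set to missing, and the fits without the lowest or with only the highest database range. Running the gene lists under settings other than the replicate block, camera and leaving out single arrays was chosen after seeing the data too. Unless fewer arrays or groups were fitted, the cause was not tested. Robust empirical Bayes and a minimum of 1.5-fold left all counts within 1.5 times. Centring over complete features, dropping the filter, complete genes only and filling missing values gave no values of their own, since no value was missing. Signal over background could not be assessed on these arrays.

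With values as deposited, counts were 67 for Het 24 h minus 0 h, 45 for Het 48 h minus 0 h, 12 for KO 24 h minus 0 h, 8 for KO 48 h minus 0 h, 9 for KO 96 h minus 0 h, 5 for the genotype by LPS interaction at 96 h, 1 for IRF4 vector minus empty vector in OCI-Ly7 and 23 for the gene lists. Quantile normalization gave 18 for KO minus Het at 96 h, 16 for KO minus Het averaged over LPS times, 17 for Het 24 h, 54 for Het 96 h, 14 for KO 24 h and 70 for KO 96 h against 0 h, 14 for the interaction at 96 h, 94 in OCI-Ly7 and 24 gene lists; Akap12 in KO minus Het at 96 h turned to -0.0214. Centring over the named features gave 14 for KO minus Het at 96 h, 15 for the average, 99 for Het 24 h, 66 for Het 48 h, 37 for KO 24 h, 15 for KO 48 h and 16 for KO 96 h against 0 h, 3 and 9 for the interactions at 48 and 96 h, 1 in OCI-Ly7 and 42 gene lists.

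Testing single features gave 128 for Het 96 h, 13 for KO 24 h and 8 for KO 48 h against 0 h and 0 in OCI-Ly7 by limma, where IRF4 turned to 0.69. Array weights gave 11 for KO minus Het at 0 h, 42 at 96 h and 15 for the average, 10 for Het 24 h, 35 for KO 24 h, 23 for KO 48 h and 102 for KO 96 h against 0 h, 5, 8 and 13 for the interactions at 24, 48 and 96 h, and 262 in OCI-Ly7. Gene medians gave 1 in OCI-Ly7. With extreme values missing, KO minus Het gave 1 at 0 h, where Gbe1 turned to -0.21, 1 at 24 h and 1 at 48 h, and KO gave 8 at 24 h, 9 at 48 h and 9 at 96 h against 0 h.

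With only the groups compared, KO minus Het gave 0 at 0 h, 1 at 48 h, 25 at 96 h and 16 on average; Het gave 0 at 24 h, 0 at 48 h and 2 at 96 h against 0 h, and KO 1 at 24 h and 63 at 96 h, since the spread then comes from these arrays alone. Leaving out the arrays of conflicting labels gave 12 for Het 48 h and 0 for KO 48 h against 0 h and 9 gene lists; taking them as Het gave 3 for the average and 0 for KO 48 h, and Hdac1 in KO minus Het at 48 h turned to -0.51. The replicate block gave 2 for KO 48 h; for the rest it gave 6, 0, 0 and 7 for KO minus Het at 0, 24, 48 and 96 h and 6 on average. The database range as a factor gave 20 for Het 96 h, 13 for KO 24 h and 11 for KO 48 h against 0 h and 6 for the interaction at 96 h.

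Without the lowest database range, KO minus Het gave 2 at 0 h, 29 at 96 h and 13 on average; Het gave 79 at 48 h and 16 at 96 h, KO 21 at 24 h, 24 at 48 h and 43 at 96 h, the interactions 2, 1 and 15 at 24, 48 and 96 h, and 26 gene lists passed. With only the highest range, KO minus Het gave 1 at 48 h and 27 at 96 h, Het 29 at 96 h, KO 3 at 24 h and 10 at 48 h, the interactions 1 and 15 at 48 and 96 h, and 9 gene lists passed, with Prdm1 in KO minus Het at 0 h at 1.00 (0.9985). In both of these, the change of Slc35a2 in Het at 96 h was -0.00175 and that of Cd79b 0.10. In OCI-Ly7 day 3 alone gave 196 and the day as a covariate 39, and IRF4 was 0.25 on day 3 alone. Camera with an estimated correlation gave 2 gene lists, 1 of the 15 past the threshold by fry and 1 other.

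Leaving out each array in turn gave 1 to 57 genes for KO minus Het at 0 h (6 with all arrays), 0 to 21 at 24 h, 0 to 0 at 48 h, 6 to 11 at 96 h (9) and 6 to 16 on average (8). It gave 5 to 71, 3 to 79 and 35 to 172 for Het at 24, 48 and 96 h against 0 h, and 2 to 9, 1 to 5 and 1 to 3 for KO. The interactions ranged from 0 to 10, 0 to 15 and 0 to 30, most without Het 0 h replicate 3. Gene lists ranged from 11 (without Het 48 h replicate 1) to 23 (without Het 0 h replicate 1), and OCI-Ly7 from 0 to 1, where IRF4 ranged from -0.258 without day 3 replicate 1 to 0.072 without day 5, with 0.021 without day 3 replicate 2 and 0.062 without day 2.

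For the genes past the threshold that the text names, 1352 values under alternatives kept direction and call, 359 kept the direction and lost the call and 3 turned; for those not past it, 1253 stayed so, 148 passed and 10 turned. For the lists, 487 kept the call and 91 lost it. The plasma cell list in KO minus Het at 96 h was past the threshold in 39 of 39 alternatives. Spearman's correlation between platforms stayed between -0.10 and -0.07 with its permutation p above the threshold, and Cd79b above the pool on 23 arrays, under the alternatives run for them.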

Other observations

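Lists that the comparisons above did not describe were small on the mouse array. At 24 h in Het, both measured MHC class II genes, H2-DMa and H2-DMb1, had a median change of -1.46 log2 units, with 0 past the threshold and 2 lower when adjusted over the list alone; in KO the median was -1.74, again with 2 lower adjusted over the list alone. At 96 h the median differences of KO from Het were -0.12 for the 2 MHC class II genes, -0.08 for the 2 switching and mutation genes, 0.34 for the 1 germinal centre gene, -0.05 for the 4 NF-kB genes, -0.05 for the 4 interferon genes and -0.13 for the 5 ribosomal and housekeeping genes, with 0 members past the threshold by limma. The MYC growth list had a median of -0.18 (fry adjusted p = 0.866), the proliferation list -0.08 (0.866) and the apoptosis list 0.06 (0.866). The immediate early stress genes, 3 in number, fell in Het between 0 and 96 h in 2 cases, with a median of -1.35.

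Markers of other cell types were few on the mouse array: 3 T and NK genes (Cd3g, Gzma and Tcra), 2 myeloid genes (Tyrobp and Cybb) and 0 erythroid and platelet genes, too few to test as lists. Cd3g lay below the pool in both genotypes at 96 h, at -2.84 ± 1.15 (SD, n = 4) in Het and -1.66 ± 0.24 (SD, n = 3) in KO. Cd79b lay above the pool on 23 of 23 arrays. At 96 h 3 of 3 T and NK genes lay higher in KO than in Het, with a median of 1.18, and 2 of 2 myeloid genes, with a median of 0.76; 0 of these markers were past the threshold by limma, and 1 myeloid gene was when adjusted over the list alone.

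In OCI-Ly7, 5 of 19 myeloid genes (fry adjusted p = 0.218), 7 of 28 T and NK genes (0.258) and 1 of 8 erythroid and platelet genes (0.127) lay above 0. Of the other lists, 9 of 15 MHC class II genes (0.857), 9 of 19 switching and mutation genes (0.837), 8 of 18 germinal centre genes (0.817), 20 of 50 proliferation genes (0.817), 13 of 30 MYC growth genes (0.83), 14 of 41 NF-kB genes (0.264), 13 of 32 interferon genes (0.480), 11 of 28 apoptosis genes (0.480), 14 of 21 immediate early genes (0.361) and 14 of 20 ribosomal and housekeeping genes (0.671) lay above 0. Of the members of these lists 0 were past the threshold by limma. The MHC class II list had a median of 0.15, a mean of -0.13 and a test towards lower values. None of the 16 human lists was past the threshold by the directional test of fry, and 3, erythroid and platelet, myeloid and plasma cell, had an unadjusted p under 0.05. The mixed test of fry, which counts changes either way, was past the threshold for most human lists, such as germinal centre (adjusted p = 0.00105), apoptosis (0.00148), mature B-cell (0.00364), plasma cell (0.00409) and ribosomal and housekeeping genes (0.0144). It does not compare the members with other genes. Of all 4604 genes, 1099 had an unadjusted limma p under 0.05, so the mixed test does not single out these lists.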
